A study of Mus musculus with 15 samples.

How the data were processed

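Single-cell RNA was measured by droplet sequencing (10x Genomics) in cells flushed from the femur of female C57/Bl6 mice, 3 days after an osteotomy (surgical division of the bone, held by an external fixator). Gap cells came from the bone pieces between the middle pins, so marrow next to the gap is part of these libraries. Per the labels, red blood cells were lysed and dead cells were removed before loading, so shares of cells describe the cells loaded and not the intact tissue. The 15 libraries form 5 groups by tissue, stiffness of the fixator and injected antibody: marrow of the uninjured femur with rigid fixation and isotype antibody (3 libraries), fracture gap with rigid fixation and isotype antibody (3), gap with rigid fixation and an antibody against CD71, the transferrin receptor (3), gap with compliant fixation and isotype antibody (5), and gap with compliant fixation and the CD71 antibody (1). Libraries are named by the sample numbers in their titles. Each compliant library carries a pair of sample numbers and each rigid library 1, so the number of samples per library cannot be told apart from fixation.

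The deposited matrices hold counts: raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.1.2 on the mm10 mouse genome, without normalization. They hold 32285 genes and 153138 barcodes in all, each barcode with 500 UMIs or more. Of the gene identifiers, 32158 (99.6%) were found in the GRCm38 annotation used for coordinates. Library totals ran from 64329546 to 91345604 UMIs. The median per barcode ran from 5317 to 7854 UMIs in 14 libraries and was 2138 in the gap library rigid CD71 6, which holds 23418 barcodes against 6764 to 11590 elsewhere. Whole-library sums of no pair of libraries within a group agree within sampling noise: the lowest chi-square per degree of freedom was 27.3, between gap rigid isotype 1 and 5, over genes with a count of 10 or more.

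Cells with at least 200 genes, at least 500 UMIs and under 10% mitochondrial UMIs were kept (144217 cells). Doublets were called per library with Scrublet as run in scanpy 1.11.5, with its automatic threshold or a fixed score of 0.25 where that failed; 2862 cells (1.98%) were called and removed. Counts were scaled to 10000 per cell and log-transformed, 2381 variable genes gave 40 principal components, and Leiden clustering on 15 neighbours at resolution 2.5 gave 54 clusters. Ribosomal, histone and mitochondrial transcripts part the libraries with sample numbers up to 10 from the later ones: the ribosomal RNA-overlapping gene model Gm42418 stood at 27959 CPM ± 4743 (SD, n = 8) in the first part of the series and at 3325 CPM ± 655 (SD, n = 7) in the second. A first clustering at resolution 1.5 divided cell types along this line. After it was seen, these genes were kept out of the clustering with cell cycle genes, the components were centred within each part and the resolution was raised, all before any comparison between groups was run. These are called the early and late part of the series. Both parts hold every group except the compliant CD71 group, and within-part differences were computed for each named gene and share.

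Clusters were named as X-like from markers fixed before the data were examined (at least 3 markers among the 30 leading genes), which gave 15 named classes. The suffix is dropped below. Left out were the called doublets and 5 clusters with over 30% called doublets (2352 cells, called doublets among them), so that 140014 cells remained. Among these, 505 cells in 2 clusters that met no definition belong to no class but count in the total that shares are taken of. No cluster met the definition of stromal, endothelial, osteoblast or chondrocyte, or skeletal muscle cells, nor that of osteoclasts, eosinophils or megakaryocytes. The doublet threshold for leaving out clusters was set after the data were seen.

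Raw counts were summed per library and class, and a library entered with 20 or more cells. Sums were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Gap was compared with marrow in the 6 rigid isotype libraries. The effect of the antibody under each fixation, the effect of fixation under isotype and the difference between the antibody effects came from 1 fit of the 12 gap libraries, which share 1 estimate of the spread; the single compliant CD71 library is assumed to vary like the others. The main classes, fixed before the data were examined, were mature neutrophil, monocyte and erythroid; other classes are secondary. Fold changes are log2 values ± SE, and group levels are mean CPM, scaled by the TMM factors, ± SD over libraries; levels in figures are unscaled CPM. On simulated counts with 200 changed genes, 4-fold changes were recovered for 69% to 98% of genes and 2-fold changes for 20% to 87%, depending on class and comparison, with 1.06% to 10.0% false calls among calls. The low end was the erythroid class of the single-library comparison.

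Shares of cells per class were compared by a two-sided exact permutation test with adjustment over the classes. With 3 libraries against 3, the smallest p is 0.1. Gene lists fixed before the data were examined (among them hemoglobin and heme synthesis, iron and heme recycling, erythroid transcription and membrane, glycolysis and hypoxia, interferon response, MHC class II, neutrophil granules, neutrophil maturation, inflammatory cytokines, repair-associated macrophage genes, immediate early genes and both cell cycle phases) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation. A list entered a test only with 5 or more members among the genes tested. Members called are counted over all genes tested and adjusted over the list alone.

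Named genes followed a rule fixed beforehand: per comparison and main class, the 4 called genes with the largest change in each direction, at 50 CPM or more in the higher group, with no overlap between the groups' libraries and at 10% or more of the gene's highest class mean; Tfrc and the hemoglobin genes in erythroid cells in every comparison; and up to 4 called members of each list past its test. The same rule was applied, after the data were seen, to the paired fit and to macrophages and plasmacytoid dendritic cells. Members that were not called are named as list examples, with their values.

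Sample numbers 1, 5 and 11 each occur on a marrow and a gap library. They were taken to mark both femora of a mouse, which the labels do not state in so many words. As a check, deviations from the group mean were correlated across genes: libraries with the same number correlated at 0.412 to 0.853 in the 3 main classes, and those with other numbers at -0.677 to 0.0412. Deviations from a mean of 3 libraries cancel out, which pushes values for other numbers down. Number 11 is also the only late one of each group. The check therefore cannot tell the same mouse from shared processing. The fit with the mouse as a block is given beside the unpaired one where it changes a call. Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, doublets kept and a stricter cell filter (500 genes, 1000 UMIs, 5% mitochondrial). Another left out genes of other classes, meaning genes whose mean in the class was under 10% of their highest class mean. Others were other sets of libraries in the fit, clusters at resolution 1.5 and leaving out each replicate. Chosen after the data were seen were the part of the series as a term and leaving out clusters with over 10% called doublets. So was leaving out the 2 compliant isotype libraries with the fewest erythroid cells.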

Results

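The series holds 15 single-cell libraries from the femur of female mice 3 days after osteotomy, with 64329546 to 91345604 UMIs per library. Marrow of the uninjured femur (n = 3) and the fracture gap (n = 3) were sampled under rigid fixation with an isotype antibody. Gap cells were also sampled under rigid fixation with an antibody against CD71 (n = 3), under compliant fixation with isotype (n = 5) and under compliant fixation with the CD71 antibody (n = 1). After filtering, 140014 cells remained, of which mature neutrophils, immature neutrophils and monocytes were the largest classes. Libraries with sample numbers up to 10 (the early part of the series) and above 10 (the late part) differ in technical transcripts, so differences within each part are given where they bear on a result. Under rigid fixation these set 2 libraries against 2 in the early part and 1 against 1 in the late part. Main classes, gene lists and tests were fixed before the data were examined. Coordinates are on GRCm38, fold changes are log2 ± SE, and levels are mean CPM ± SD over libraries.

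The gap held fewer erythroid, B, T and plasmacytoid dendritic cells per 100 cells than marrow of the uninjured femur, and more monocytes and macrophages. Erythroid cells made up 6.01% ± 0.393 (SD, n = 3) of gap cells and 9.26% ± 1.33 (n = 3) of marrow cells, and monocytes 9.501% ± 0.1797 against 8.62% ± 0.560. B cells stood at 3.23% ± 0.899 in gap and 5.07% ± 0.907 in marrow, T cells at 3.22% ± 0.147 and 4.05% ± 0.276, plasmacytoid dendritic cells at 1.44% ± 0.294 and 2.81% ± 0.794, and macrophages at 0.703% ± 0.231 and 0.342% ± 0.0784. Gap and marrow libraries did not overlap for these 6 classes, each with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.214). Within all 3 pairs of libraries with the same sample number the gap also held more immature neutrophils (by 2.72 to 4.63 percentage points), mature neutrophils (0.883 to 3.08) and granulocyte-monocyte progenitors (0.632 to 2.55). The groups overlapped for these (exact permutation p = 0.2 each), and an exact sign flip over 3 pairs cannot go below p = 0.25. All 3 pairs also had 1 sign for B cell precursors (-1.49 to -0.688), plasma cells (-0.281 to -0.0252) and dendritic cells (0.0719 to 0.191). The groups overlapped for these as well (exact permutation p = 0.5, 0.6 and 0.3). The erythroid difference was -3.61 percentage points within the early part of the series and -2.54 within the late part. The monocyte difference was 1.09 and 0.457. Within pairs of the same sample number the macrophage difference ran from 0.0383 to 0.587 percentage points. It was lowest for number 5, with 36 macrophages in either library. Among the erythroid clusters, the cluster led by Car1, the carbonic anhydrase of early erythroid cells, held 0.932 ± 0.111 cells per 100 non-erythroid cells in gap and 1.69 ± 0.209 in marrow. The hemoglobin-rich cluster led by Tmcc2 held 2.13 ± 0.242 and 3.88 ± 1.00 (exact permutation p = 0.1 each). The groups overlapped for the other 3 erythroid clusters: 2.44 ± 0.337 and 3.30 ± 0.822 for that led by Hemgn (exact permutation p = 0.2), 0.767 ± 0.571 and 1.25 ± 0.982 for that led by Hbb-bs (exact permutation p = 0.5), and 0.130 ± 0.172 and 0.106 ± 0.142 for the small one led by Hba-a2 and Hba-a1 (exact permutation p = 0.7). Red blood cell lysis came before loading, and gap cells include those of marrow between the pins, so these shares are of the cells loaded.

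**Figure D1:**
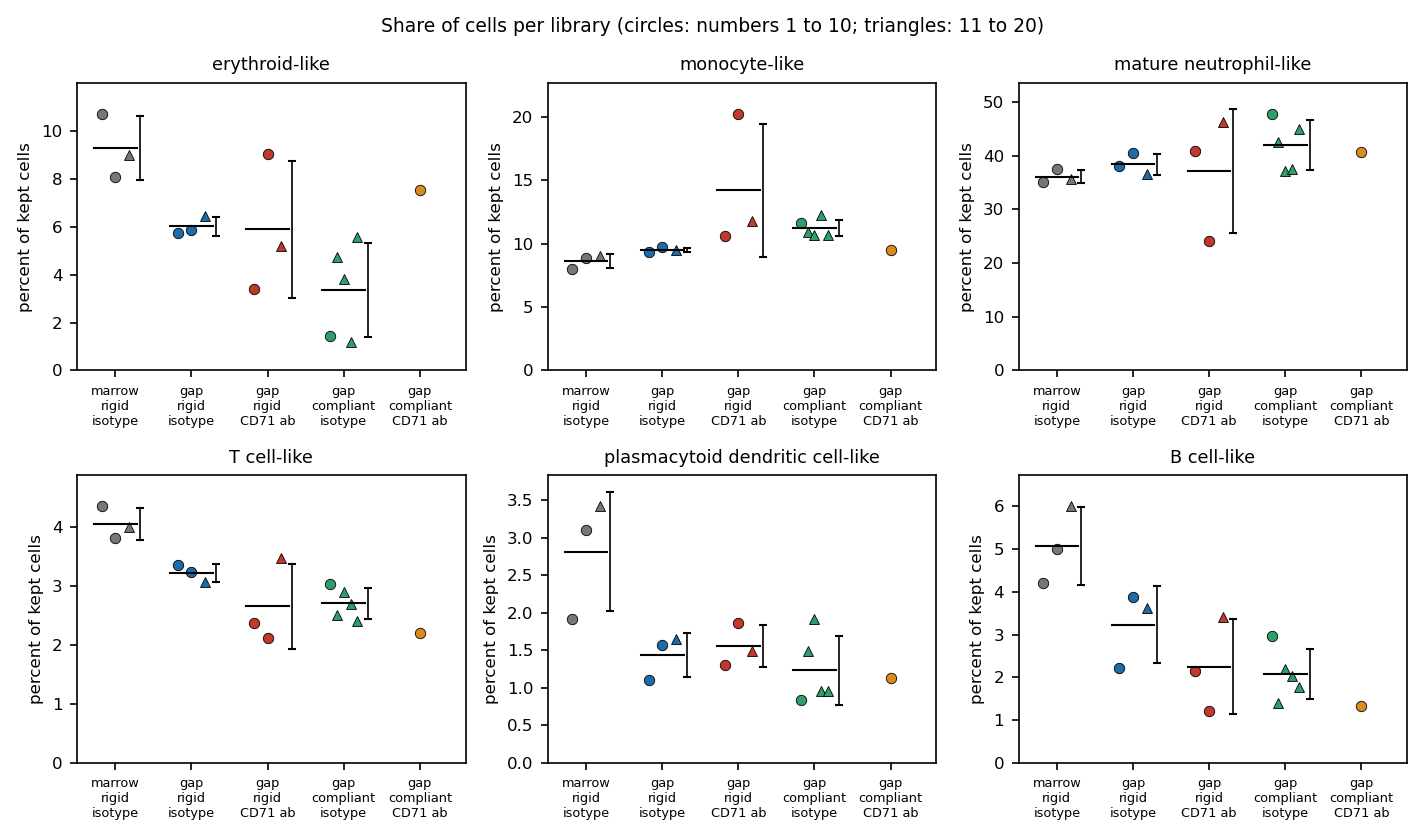
Percent of cells per library (vertical axis) for 6 classes in the 5 groups (horizontal axis), with libraries as points (circles up to sample number 10, triangles above), horizontal lines as group means and vertical bars as SD. Erythroid cells made up 9.26% ± 1.33 (SD, n = 3) of marrow and 6.01% ± 0.393 (n = 3) of gap cells under rigid fixation with isotype.

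Gap neutrophils carried more RNA of stefin A genes, which encode inhibitors of cysteine proteases. Stfa2 (ENSMUSG00000022902, chromosome 16: 36403992 to 36408457) stood at 190 CPM ± 35.0 (n = 3) in gap and 61.3 CPM ± 13.3 (n = 3) in marrow, a change of 1.63 ± 0.17 (adjusted p = 0.0135). Stfa1 (ENSMUSG00000071562, chromosome 16: 36276951 to 36285373) stood at 300 CPM ± 31.0 and 128 CPM ± 17.1, a change of 1.23 ± 0.12 (adjusted p = 0.00994). These were the 2 genes called of 10063 tested, both higher (19 with DESeq2, 64 without a low-count filter, 14 with the part of the series as a term, 0 with all 15 libraries in the fit, and 0 to 5 with single libraries left out, 0 without marrow 5). With the mouse as a block, 111 genes were called, 51 higher and 60 lower. Among the higher ones were Stfa1, Stfa2 and their neighbours on chromosome 16: Cstdc5 (ENSMUSG00000071561, 1.38, adjusted p = 8.0e-10), Stfa3 (ENSMUSG00000054905, 1.16, adjusted p = 2.1e-07) and Stfa2l1 (ENSMUSG00000059657, 0.85, adjusted p = 4.7e-08). The stefin A genes are close paralogs, so reads may be shared among them. In the same blocked fit the chemokine gene Ccl3 (0.89, adjusted p = 0.00138) and the cytokine gene Il1b (0.45, adjusted p = 0.00103) rose. Osm (-0.42, adjusted p = 0.00508), the lysozyme gene Lyz2 (-0.30, adjusted p = 1.5e-05) and Chil3 (-0.33, adjusted p = 5.2e-05) fell. None of these 5 genes was called without the block. Shares of some clusters within the class differed as well, and these shares were not tested. Clusters led by stefin A genes are set apart by the same RNA, so they are not separate support. The cluster led by Cstdc4 and Stfa2 held 9.05% ± 0.439 of mature neutrophils in gap and 5.67% ± 1.18 in marrow, that led by Cstdc5 and Stfa1 0.465% ± 0.163 and 0.0800% ± 0.0176, that led by Cxcl2 and Ccl3 1.37% ± 0.151 and 0.205% ± 0.0760, and that led by Mmp8 and Mmp9 20.0% ± 0.449 and 25.2% ± 3.08. Changes in the class sum therefore include changes in this mix.

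Among the fixed lists in neutrophils, inflammatory cytokines and NF-kB targets were higher in gap for 33 of 41 members (0 called, 4 higher and 1 lower with the block, adjusted p = 0.00094, or adjusted p = 0.345 with an estimated correlation). Neutrophil granules were lower for 22 of 29 (0 called, 6 lower and 1 higher with the block, adjusted p = 0.012, or adjusted p = 0.361 with an estimated correlation). Neutrophil maturation and release genes were higher for 18 of 25, with Stfa2 among them (adjusted p = 0.0078, or adjusted p = 0.179 with an estimated correlation). All 22 erythroid transcription and membrane genes were lower (adjusted p = 3.1e-14, or adjusted p = 0.172 with an estimated correlation). So were 15 of 16 hemoglobin and heme synthesis genes (adjusted p = 1.3e-10, or adjusted p = 0.172 with an estimated correlation). Hemoglobin RNA within neutrophils, which do not make it, stood at 643 CPM ± 212 in gap and 1112 CPM ± 68.6 in marrow.

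**Figure D2:**
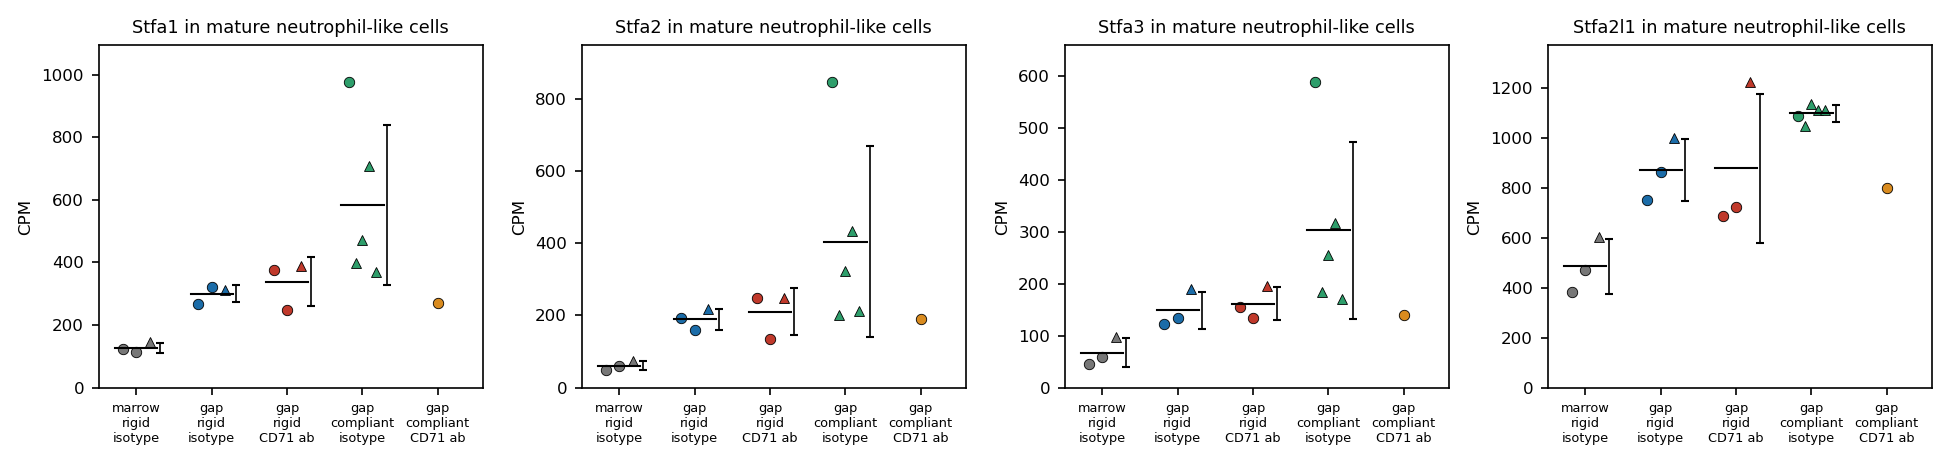
Stefin A genes in mature neutrophils: CPM per library (vertical axis) in the 5 groups (horizontal axis), with libraries as points (circles up to sample number 10, triangles above), horizontal lines as group means and vertical bars as SD. Stfa1 averaged 127 CPM ± 15.3 (SD, n = 3) in marrow and 300 CPM ± 28.3 (n = 3) in gap under rigid fixation with isotype.

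In monocytes, DNA replication genes were higher and interferon response genes lower in gap. Of the cell cycle S phase list, 42 of 43 members were higher (adjusted p = 6.0e-09, or adjusted p = 0.667 with an estimated correlation). Of the interferon response list 48 of 49 were lower (adjusted p = 1.7e-05, or adjusted p = 0.667 with an estimated correlation). With the block, 6 interferon members fell, among them Ifi27l2a (-0.42, adjusted p = 0.0068), Bst2 (-0.38, adjusted p = 0.02) and Irf7 (-0.43, adjusted p = 0.028), the master regulator of type I interferon. Without it edgeR called 0 of 10935 monocyte genes (308 at unadjusted p under 0.05; DESeq2 called 2), against 37 with it, 13 higher and 24 lower. In erythroid cells 0 of 9862 genes were called (473 unadjusted, 1 with DESeq2 and 9 with the block). The unadjusted counts of both classes are under 0.05 of the genes tested, the share that chance alone would give with unpaired libraries. They come from the fit without the block. Libraries with the same sample number deviated together, which widens the spread in that fit. These counts therefore cannot show that only chance is at work. Tfrc (ENSMUSG00000022797, chromosome 16: 32608920 to 32632794), which encodes CD71, stood at 750 CPM ± 75.4 in gap and 669 CPM ± 55.9 in marrow erythroid cells (0.16 ± 0.11, adjusted p = 0.981). Hbb-bs was at 0.10 ± 0.16, Hbb-bt at 0.07 ± 0.15, Hba-a1 at 0.15 ± 0.19 and Hba-a2 at 0.07 ± 0.19, none called. The cell cycle G2M list was higher for 51 of 53 members in erythroid cells (0 called, adjusted p = 6.9e-13, or adjusted p = 0.931 with an estimated correlation).

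Gap macrophages had high levels of Spp1 (osteopontin) and Arg1 (arginase 1), which were nearly absent from marrow macrophages, and low levels of the iron exporter Slc40a1 (ferroportin). Spp1 (ENSMUSG00000029304, chromosome 5: 104435118 to 104441050) gave 14581 counts in gap and 1 in marrow, 1842-fold by level with a 95% counting interval of 331 to 72775. Counting intervals, here and below, pool the counts of the libraries of a group and leave out the spread between libraries. Arg1 (ENSMUSG00000019987, chromosome 10: 24915221 to 24927484) gave 2634 counts in gap and 0 in marrow, at least 111-fold higher. Slc40a1 (ENSMUSG00000025993, chromosome 1: 45908068 to 45926523) stood at 139 CPM ± 69.5 in gap and 2507 CPM ± 581 in marrow (-4.25 ± 0.35, adjusted p = 1.4e-06). Spic (ENSMUSG00000004359), the transcription factor of iron-recycling macrophages, stood at 24.7 CPM ± 12.4 and 395 CPM ± 128 (-3.92 ± 0.38, adjusted p = 7.1e-06). The transferrin gene Trf (ENSMUSG00000032554) stood at 178 CPM ± 19.0 and 1270 CPM ± 166 (-2.84 ± 0.24, adjusted p = 1.7e-06). The fibronectin gene Fn1 gave 3417 counts in gap and 2 in marrow (216-fold by level, 95% counting interval 59.7 to 1783), and the monocyte chemokine gene Ccl2 1140 and 1 (144-fold, 25.8 to 5694), so their folds are known only roughly. The protease gene Ctsl stood at 2707 CPM ± 550 in gap and 115 CPM ± 38.6 in marrow, Ccr3 at 5.14 CPM ± 2.61 and 622 CPM ± 256, and Itgad at 7.59 CPM ± 6.80 and 420 CPM ± 185 (adjusted p from 1.7e-07 to 1.1e-05 for these 5 genes).

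Of the repair-associated macrophage list, 17 of 30 members rose and 5 fell (adjusted p = 2.5e-06, or adjusted p = 0.0498 with an estimated correlation). Of glycolysis and hypoxia genes, 14 of 23 rose and 1 fell (adjusted p = 2.5e-06, or adjusted p = 0.0498 with an estimated correlation). Pkm stood at 1.67 ± 0.25, Tpi1 at 1.86 ± 0.28, Ldha at 1.72 ± 0.27 and Eno1 at 1.96 ± 0.31. Inflammatory cytokines and NF-kB targets rose for 11 of 23 and fell for 1 (adjusted p = 0.00033, or adjusted p = 0.0614 with an estimated correlation). Iron and heme recycling genes fell for 6 of 17 (adjusted p = 0.00075, or adjusted p = 0.26 with an estimated correlation). Neutrophil granule genes fell for 16 of 22 and rose for 1 (adjusted p = 2.1e-08, or adjusted p = 0.26 with an estimated correlation). In all, 221 of 2859 genes were higher and 295 lower. This class is 1 cluster, with 83 marrow and 166 gap cells, and Spp1, Arg1 and Dab2 also lead it against all other cells. Marrow macrophages had median totals of 757 to 1432 UMIs against 5661 to 10103 in gap, and S100 and granule transcripts of neutrophils at 138337 CPM ± 50113 against 14839 CPM ± 8575. These sums are 38.0% of the mature neutrophil level in marrow and 4.06% in gap. Neutrophil RNA at such a level would dilute macrophage transcripts in marrow, so rises in gap may include this dilution.

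**Figure D3:**
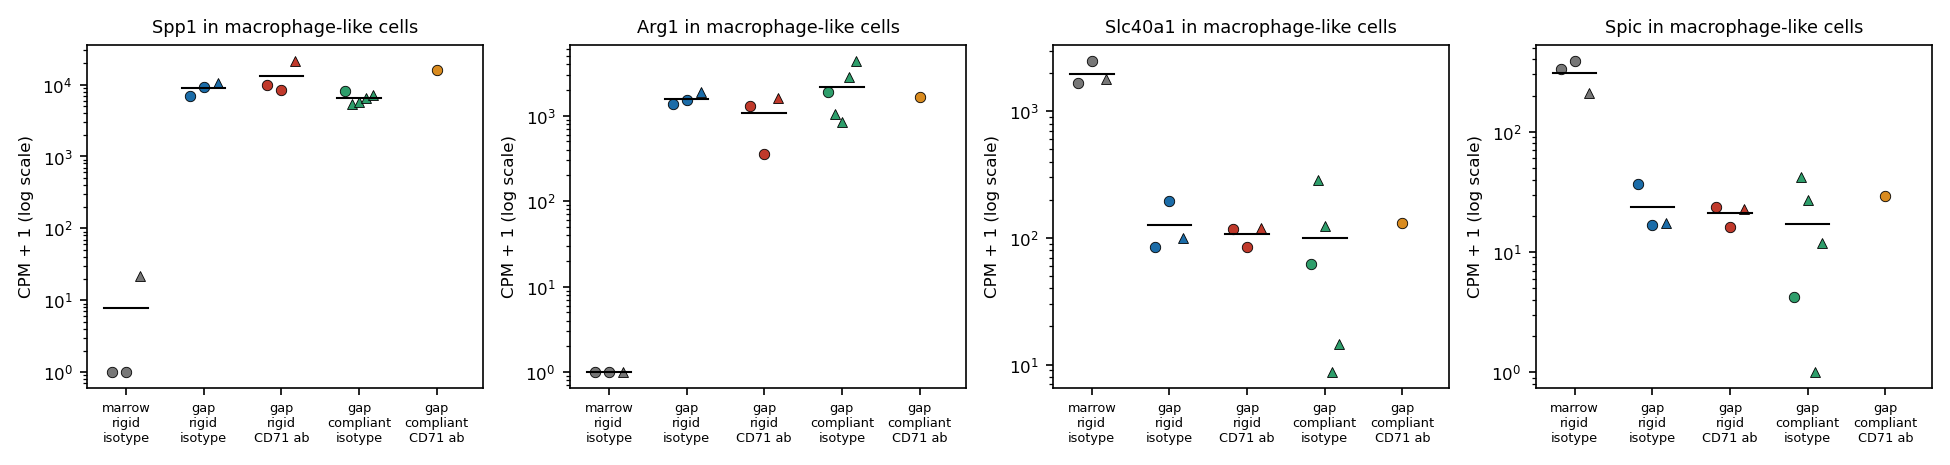
Spp1, Arg1, Slc40a1 and Spic in macrophages: CPM plus 1 per library on a log scale (vertical axis) in the 5 groups (horizontal axis), with libraries as points (circles up to sample number 10, triangles above) and horizontal lines as group means. Slc40a1 averaged 1979 CPM ± 447 (SD, n = 3) in marrow and 125 CPM ± 60.8 (n = 3) in gap under rigid fixation with isotype.

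Plasmacytoid dendritic cells of the gap carried more RNA of mitosis genes and less of antigen presentation genes. Of the G2M list, 30 of 52 members rose and none fell (adjusted p = 4.6e-33, or adjusted p = 0.231 with an estimated correlation). Cdc20 (ENSMUSG00000006398) stood at 80.7 CPM ± 11.6 in gap and 26.8 CPM ± 4.10 in marrow (1.63 ± 0.18), beside Ccnb1 (1.18 ± 0.18) and Ube2c (1.18 ± 0.17). MHC class II genes fell for 5 of 12 (adjusted p = 1.5e-06, or adjusted p = 0.231 with an estimated correlation). H2-Ab1 (ENSMUSG00000073421) stood at 393 CPM ± 46.3 and 763 CPM ± 107 (-0.96 ± 0.13), Cd74 at -0.87 ± 0.12 and H2-Aa at -0.83 ± 0.11. The interferon-induced gene Isg15 (-1.81 ± 0.22) and Lag3 (-1.12 ± 0.21) fell as well. Neutrophil granule genes rose for 15 of 26 (adjusted p = 4.3e-14, or adjusted p = 0.231 with an estimated correlation), with Chil3 at 1.26 ± 0.18. This rise was mostly lost without the cluster of the class in which 17.6% of cells were called doublets, which held 8.43% ± 0.431 of the class in gap and 2.59% ± 1.38 in marrow: a median of 9.32% of the difference was kept, and Chil3 fell to 0.68 and was not called. Cdc20 (1.67) and H2-Ab1 (-0.89) held. S100 and granule transcripts summed to 29987 CPM ± 6812 in gap and 13794 CPM ± 6359 in marrow. Hemoglobin RNA in these cells summed to 405 CPM ± 157 in gap and 823 CPM ± 23.3 in marrow. Hbb-bs (-1.01) thus fell about as much as H2-Ab1, and Spp1, which leads the macrophage cluster, rose (2.08). Whether RNA of other cells gives part of the MHC class II fall was not tested. In all 141 genes were higher and 63 lower of 8413, against 320 and 232 with the block, and 5 were called with the stricter cell filter.

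Under rigid fixation, libraries with the CD71 antibody disagreed in their erythroid share, and Tfrc in erythroid cells was lower without passing the test. Erythroid cells made up 5.88% ± 2.86 (n = 3) of cells with the antibody and 6.01% ± 0.393 (n = 3) with isotype (exact permutation p = 1), with a difference of 0.427 percentage points in the early part of the series and -1.25 in the late part. Libraries 2 and 12 (3.41% and 5.21%) lay below every isotype library (5.73% to 6.46%) and library 6 (9.01%) above, so that the difference of -0.132 became -1.70 without library 6. Tfrc stood at 473 CPM ± 96.0 with the antibody and 795 CPM ± 77.2 with isotype (-0.75 ± 0.23, adjusted p = 0.0786), and its difference was -0.88 and -0.54 within the early and late parts. Hbb-bs (ENSMUSG00000052305, chromosome 7: 103826534 to 103828096) stood at -0.58 ± 0.22 (adjusted p = 0.131). Monocytes made up 14.2% ± 5.27 against 9.501% ± 0.1797 (exact permutation p = 0.1, adjusted p = 0.667), a difference of 5.88 and 2.31 percentage points within the early and late parts. The single library 6 reached 20.2%, and without it the difference fell from 4.69 to 1.66. Mature neutrophils stood at 37.1% ± 11.6 against 38.4% ± 2.03 (exact permutation p = 1). Library 6 (24.1%) sets the direction here: libraries 2 and 12 (40.9% and 46.4%) lay above every isotype library (36.5% to 40.5%), and the difference of -1.24 became 5.27 without library 6.

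In erythroid cells 5 genes rose with the antibody and 1 fell, of 11397 (2698 at unadjusted p under 0.05; DESeq2 called 747): Cstdc4 (2.41 ± 0.36), Wfdc17 (2.35 ± 0.39), Rapgef2 (2.09 ± 0.35), Ifngr2 (1.64 ± 0.25), Selplg (1.35 ± 0.22) and Samd11 (-1.16 ± 0.19), each with adjusted p = 0.0484. Cstdc4 and Wfdc17 are among the leading genes of mature neutrophil clusters, and Selplg is on the neutrophil maturation list. How much of these rises neutrophil RNA would give was not computed. The 2698 genes at unadjusted p under 0.05 are over 0.05 of the genes tested, the share that chance alone would give if genes varied independently. Of the genes called only Selplg was named by the rule, and the others are named because they make up the count. This count is unstable. It was 0 with the part of the series as a term, with genes of other classes left out, with doublets kept, with only the 2 groups in the fit and without any of the isotype libraries. It was 607 with stricter cells, 1182 without a low-count filter, 279 without CD71 12 and 1828 without CD71 2. All 53 G2M genes were lower with the antibody (adjusted p = 5.0e-21, 31 called adjusted over the list alone, or adjusted p = 0.208 with an estimated correlation). So were all 16 hemoglobin and heme synthesis genes (adjusted p = 6.3e-10, 15 called adjusted over the list alone, or adjusted p = 0.208 with an estimated correlation). Of 28 erythroid transcription and membrane genes, 26 were lower, such as Slc4a1 (-0.75 ± 0.23) (adjusted p = 1.1e-11, or adjusted p = 0.208 with an estimated correlation). Neutrophil granule genes were higher for 28 of 29 (adjusted p = 5.9e-08, or adjusted p = 0.219 with an estimated correlation). S100 and granule transcripts in erythroid cells summed to 64227 CPM ± 38764 with the antibody and 24169 CPM ± 8269 with isotype. A low-UMI erythroid cluster with 14.7% called doublets held 51.3% of the erythroid cells of library 6. By group it held 28.2% ± 22.0 of the class with the antibody and 11.6% ± 7.82 with isotype. The cluster led by Hemgn held 24.6% ± 15.4 and 38.5% ± 7.65, and that led by Car1 22.4% ± 4.48 and 14.5% ± 0.847. The lists may therefore compare different mixes of cells.

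In neutrophils and monocytes the antibody went with higher interferon response genes. Of 46 tested in neutrophils, 44 were higher (adjusted p = 2.3e-16, or adjusted p = 0.631 with an estimated correlation). Ifitm3 (ENSMUSG00000025492) stood at 1494 CPM ± 284 against 1054 CPM ± 118 (0.50 ± 0.15, adjusted p = 1) and Oas2 at 0.69 ± 0.27. In monocytes 50 of 52 were higher (adjusted p = 1.9e-06, or adjusted p = 0.7 with an estimated correlation). So were 14 of 16 MHC class II genes (adjusted p = 0.00043, or adjusted p = 0.645 with an estimated correlation), with Cd74 at 1.28 ± 0.38 and H2-Aa at 1.86 ± 0.60. edgeR called 0 of 11139 neutrophil genes (220 unadjusted, 0 with DESeq2) and 0 of 11999 monocyte genes (423 unadjusted, 0 with DESeq2). Both unadjusted counts are below what chance alone would give. A single monocyte cluster with over 10% called doublets held 63.0% of the monocytes of library 6, against 9.85% and 14.1% in the other CD71 libraries and 9.30% ± 1.78 (n = 3) with isotype.

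**Figure D4:**
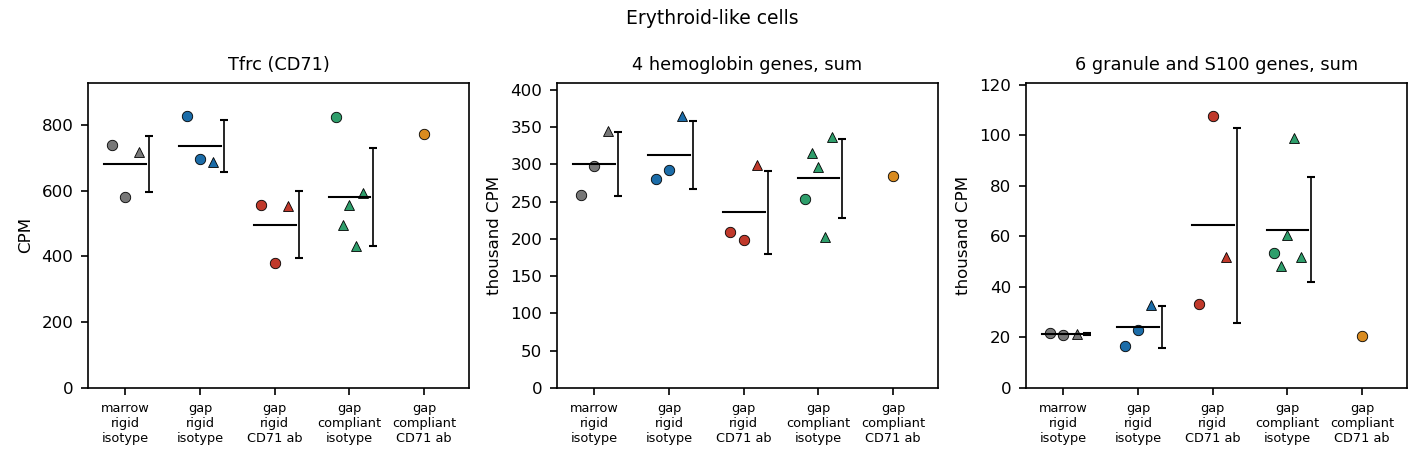
Tfrc, the sum of 4 hemoglobin genes and the sum of 6 S100 and neutrophil granule genes in erythroid cells: CPM per library (vertical axis) in the 5 groups (horizontal axis), with libraries as points (circles up to sample number 10, triangles above), horizontal lines as group means and vertical bars as SD. Tfrc averaged 737 CPM ± 79.4 (SD, n = 3) with isotype and 497 CPM ± 102 (n = 3) with the CD71 antibody under rigid fixation.

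Compliant gaps with isotype held fewer erythroid and T cells and more monocytes per 100 cells than rigid gaps with isotype. Erythroid cells made up 3.34% ± 1.96 (n = 5) against 6.01% ± 0.393 (n = 3) (exact permutation p = 0.0536; the difference of -2.67 percentage points became -1.31 without libraries 7-8 and 17-18, which hold the fewest), monocytes 11.2% ± 0.669 against 9.501% ± 0.1797 (p = 0.0179) and T cells 2.70% ± 0.262 against 3.22% ± 0.147 (p = 0.0357), each with adjusted p = 0.161. Within the early and late parts of the series the differences were -4.37 and -2.63 percentage points for erythroid cells, 2.10 and 1.67 for monocytes and -0.263 and -0.442 for T cells. The early part sets a single compliant library (7-8, with 1.42% erythroid cells) against 2 rigid ones and the late part 4 against 1. Each compliant library carries a pair of sample numbers, which cannot be parted from fixation.

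Immediate early genes, which respond to stimulation and to tissue dissociation, were lower under compliant fixation for 36 of 37 members in neutrophils (adjusted p = 1.3e-09, or adjusted p = 0.354 with an estimated correlation) and 31 of 34 in monocytes (adjusted p = 1.8e-05, or adjusted p = 0.363 with an estimated correlation). Examples are Nr4a1 (ENSMUSG00000023034) at 1.77 CPM ± 0.567 against 4.74 CPM ± 0.271 (-1.42 ± 0.30, adjusted p = 0.421, or 0.025 with the part of the series as a term) and Egr1 (-1.27 ± 0.36, adjusted p = 0.717) in neutrophils and Jun (-0.94 ± 0.21, adjusted p = 0.421) in monocytes. The chemokine gene Cxcl2 stood at 59.4 CPM ± 12.1 against 140 CPM ± 68.5 in neutrophils (-1.24 ± 0.36, adjusted p = 0.717). In erythroid cells all 43 S phase genes were lower (adjusted p = 7.4e-15, 29 called adjusted over the list alone, or adjusted p = 0.393 with an estimated correlation). Neutrophil granule genes were higher for 28 of 29 (adjusted p = 5.8e-09, or adjusted p = 0.393 with an estimated correlation). S100 and granule transcripts summed to 62529 CPM ± 20769 against 24169 CPM ± 8269. The mix of erythroid clusters differs too: the low-UMI cluster with 14.7% called doublets held 26.8% ± 13.8 of the class under compliant and 11.6% ± 7.82 under rigid fixation, and the cluster led by Hemgn 23.0% ± 5.95 and 38.5% ± 7.65. Tfrc stood at 574 CPM ± 165 against 795 CPM ± 77.2 (-0.47 ± 0.21, adjusted p = 0.221). edgeR called 0 genes in neutrophils (644 unadjusted; DESeq2 15), monocytes (1216 unadjusted; DESeq2 19) and erythroid cells (2292 unadjusted; DESeq2 356). By edgeR, erythroid genes numbered 1286 with only the 2 groups in the fit and 683 without a low-count filter, and neutrophil genes 11 with the part of the series as a term, so the count of 0 depends on the fit.

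Under compliant fixation the single library with the CD71 antibody held more erythroid cells and B cell precursors than any isotype library. Erythroid cells made up 7.51% (n = 1) against 3.34% ± 1.96 (n = 5, 1.19% to 5.56%). B cell precursors made up 4.72% against 1.52% (0.325% to 2.62%) and monocytes 9.49% against 11.2% (10.7% to 12.2%). The library also lay above every isotype library for hematopoietic stem or progenitor cells (1.86% against 0.879% to 1.38%) and basophils or mast cells (1.35% against 0.910% to 1.23%). It lay below every one for B cells, T cells, plasma cells and immature neutrophils, as for monocytes. Extremes were thus not particular to erythroid cells and B cell precursors. Tfrc stood at 801 CPM against 574 CPM ± 165 (0.48 ± 0.30, adjusted p = 0.815), and -0.02 against the isotype library of the same part of the series. Hbb-bs stood at 0.09 ± 0.30, Hbb-bt at 0.10 ± 0.30, Hba-a1 at 0.05 ± 0.33 and Hba-a2 at -0.00 ± 0.34. In erythroid cells 51 of 53 G2M genes were higher (adjusted p = 4.9e-15, or adjusted p = 0.276 with an estimated correlation). Of 29 neutrophil granule genes, 24 were lower (adjusted p = 3.2e-13, or adjusted p = 0.276 with an estimated correlation), with Ly6g at -2.01 ± 0.60 and Lcn2 at -1.76 ± 0.56. The low-UMI cluster with 14.7% called doublets held 5.81% of erythroid cells with the antibody and 26.8% ± 13.8 with isotype, and the cluster led by Hemgn 38.0% and 23.0% ± 5.95, so the lists compare different mixes of cells. In neutrophils, 33 of 35 oxidative phosphorylation genes were lower (adjusted p = 6.2e-10, or adjusted p = 0.544 with an estimated correlation). edgeR called 0 genes in erythroid cells (718 unadjusted; DESeq2 0), neutrophils (682 unadjusted; DESeq2 13) and monocytes (492 unadjusted; DESeq2 0). With 1 library, differences between mice cannot be told from the antibody.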

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

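The tests on the part of the series, on neutrophil RNA and on the differences kept were chosen after the results they bear on were seen. An earlier test for RNA of other cells was replaced by the neutrophil RNA test after its result was known. It left out genes whose mean in the class was under 10% of their highest class mean. With those genes left out, 389 erythroid genes were called against the 433 described next and 514 macrophage genes against 516. In plasmacytoid dendritic cells 154 genes were called against 204. Neutrophil RNA was put at up to 17.6% of the mature neutrophil level in erythroid cells and 38.0% in marrow macrophages. Neutrophil transcripts can therefore pass that cut, so genes kept in these classes do not speak against RNA of other cells. Both tests are given, though the earlier one cannot decide the erythroid or macrophage case. Counts of genes called were first taken as the test of doublet-prone clusters, the part and library 6. They were replaced by the differences kept, because every erythroid call lies close to the threshold and because a count does not say which genes are still called.

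A difference between groups picked out the effect of the CD71 antibody in erythroid cells: 433 of 11397 genes changed differently under compliant than under rigid fixation, 120 more upward and 313 more downward, and 16 gene lists differed (0 with an estimated correlation). The downward set includes genes expressed by neutrophils, such as Cstdc4 (-4.23 ± 0.66), C5ar1 (-3.64 ± 0.64), S100a6 (-3.26 ± 0.56) and Retnlg (-3.15 ± 0.56). It also holds Id2 (-3.41 ± 0.65) and Ifngr2 (-2.54 ± 0.44), and the upward set holds the mitosis gene Kif14 (1.58 ± 0.28). These are examples from the genes with the lowest p, not a count over either set. All 433 lie just under the threshold (adjusted p from 0.0473 to 0.0499), so a small shift can end the calls: 1 remained with doublets kept, and leaving out any isotype library but rigid 11 left 0 or 1. The median size of their differences was 2.14 (median SE 0.51). With doublet-prone clusters left out 2 genes were called, at a median size of 1.37 (median SE 0.53) and with a median of 71.9% of the difference kept (quartiles 57.3% and 96.5%). These calls ended as the differences shrank, and the explanation stays open. With the part of the series as a term 1 gene was called, at 2.09 (median SE 0.56) and with 98.8% kept (quartiles 93.0% and 104%). These calls ended as the SE grew while the differences hardly moved, which speaks against a shift common to all groups of a part as what made the differences. It is not taken to exclude the part, since the calls were not kept and, within the early part, the compliant side is 1 library against 1. Without library 6, the CD71 library with the most barcodes, 390 genes were called, 343 of the 433 among them, and 82.9% was kept (quartiles 78.4% and 87.9%), which argues against that library alone. S100 and granule transcripts put neutrophil RNA at 17.6% of the mature neutrophil level with the antibody and 6.62% with isotype under rigid fixation. Under compliant fixation they put it at 6.14% and 16.3%. Neutrophil RNA at these levels would give at least 50% of the difference for 287 of the 433 genes (66.3%). This is most of the set, yet short of the share set for a cause. The test therefore cannot decide, and neutrophil RNA stays a candidate cause for these differences. The compliant antibody group is a single library, so a biological difference cannot be told from a difference between mice.

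Macrophages of gap and marrow differed at 516 of 2859 genes. S100 and granule transcripts put neutrophil RNA at 38.0% of the mature neutrophil level in marrow macrophages and at 4.06% in gap ones. Such RNA would give at least 50% of the difference for 25 of the 221 genes higher in gap (11.3%) and for 86 of the 295 lower ones (29.2%). These shares argue against neutrophil RNA as the cause of most of either set. Neutrophil RNA stays a candidate for granule genes such as Ngp (-3.89 ± 0.46) and Ltf (-3.85 ± 0.47). Marrow macrophages were few and shallow, and a mixture of different macrophage types in a single cluster was not tested. The real split called the most genes of the 10 ways to divide the 6 libraries (1 of 10 as large, highest other 0), but 10 splits are too few for a share under 0.05.

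Plasmacytoid dendritic cells of gap and marrow differed at 204 genes. Without the doublet-prone cluster 164 genes were called, 136 of the 204 among them, and 10 of the 204 turned direction. The 2 parts of the set behave differently. Of the 189 genes outside the neutrophil granule list, 174 could be tested and kept a median of 101% of the difference (quartiles 88.7% and 108%), which argues against doublet-prone cells as their main cause. Of the 15 granule genes, 14 could be tested and kept 9.32% (quartiles -15.4% and 51.4%). Their median size fell from 0.98 (median SE 0.18) to 0.26 (median SE 0.24), 6 turned direction and 1 was still called, so doublet-prone cells stay a candidate cause for them. Neutrophil RNA would give at least 50% of the difference for 46 of the 204 (22.5%), which argues against it for most of the set. The stricter cell filter left 5 genes, and whether this comes from the cells removed was not tested. Of 10 splits 1 called as many, with 4 as the highest other.

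The remaining counts were set against other splits of the same libraries in the same way. For gap against marrow, 1 of 10 splits called as many genes in neutrophils (highest other 1). For the antibody under rigid fixation 2 of 10 did in erythroid cells, where another split (isotype 1 and 5 with CD71 2 against the rest) called 152 genes against 6 for the real one, which points to another structure among these libraries. These splits are too few for a share under 0.05. With the mouse as a block, gap and marrow can be swapped within mice in 4 ways. The real one called the most genes, 111 in neutrophils (highest other 19), 37 in monocytes (0), 9 in erythroid cells (2), 512 in macrophages (0) and 552 in plasmacytoid dendritic cells (0), and 4 ways are again too few. Where the real split called 0 genes, every split is as large by construction and the share says nothing about chance. This holds for gap against marrow in monocytes (10 of 10, highest other 1) and erythroid cells (10 of 10, highest other 6), for the antibody under rigid fixation in neutrophils and monocytes (10 of 10, highest other 0), and for compliant against rigid fixation in neutrophils, monocytes and erythroid cells (56 of 56, highest other 45, 51 and 37). The split with 45, 51 and 37 genes sets the late part of the series against the early part, so it shows the part as a structure of the libraries. Splits that do not follow the part called up to 42 genes in neutrophils (5, 11, 13-14, 15-16 and 19-20 against 1, 7-8 and 17-18; the next 12), up to 2 in monocytes and 0 in erythroid cells. With the part as a term, compliant against rigid fixation called 11 genes in neutrophils and 0 in monocytes and erythroid cells.

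Other results were picked out by value alone. Basophils or mast cells had 17 genes whose antibody change differed between fixations, among them Ifitm6 (-2.85 ± 0.47), Mmp9 (-2.49 ± 0.41) and Hist1h4h (3.39 ± 0.63). The downward genes include transcripts of neutrophils and their precursors (S100a6, Hp and Elane as well), and all 5 upward genes are histone genes. Other histone genes were higher in the early part of the series (Hist1h1e 2.80 times, Hist1h2ap 2.18 times), where the single compliant CD71 library lies. With the part as a term 11 genes were called, 1 upward and 10 downward. Neither source was tested further. Lists whose antibody change differed numbered 8 in neutrophils and 9 in monocytes, and 0 in either with an estimated correlation. An unnamed cluster led by Ifit1, Ifit3 and Ifit3b held 1.76% of the cells of compliant isotype library 19-20, far from the other 4 libraries of its group (0.012% to 0.147%). It was the 1 measure past a Dixon test of 25 measures and 50 ends, where about 1 in 20 would pass by chance.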

How the results depend on the processing

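Between settings, 206 counts of genes called kept within 1.5 times and 71 moved. Of shares, 148 were kept and 5 reversed. Kept means the same direction or, for the comparison with a single antibody library, a shift under the SD of its isotype libraries. Direction was not checked in that comparison, so its reversals are not counted. Of named genes, 1180 kept their call or stayed uncalled, 115 weakened, 4 strengthened and 22 reversed. Of lists, 918 kept their call, 253 weakened and 5 reversed. With an estimated correlation 122 of 124 list calls weakened. The stricter cell filter left too few marrow macrophages to fit. Where no cause is given, the cause was not tested. Settings on the part of the series (early or late), doublet-prone clusters and the 2 small compliant libraries were chosen after seeing the data.

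Gap against marrow: neutrophil genes (2) were 19 with DESeq2, 64 without a low-count filter, 14 with the part as a term, 111 with the mouse as a block and 0 with all 15 libraries in the fit; leaving out a library gave 0 (marrow 5) to 5 (gap 11). Monocyte genes (0) were 2 with DESeq2, 11 without the filter, 1 with doublets kept and 37 with the block; 0 to 1 (gap 11). Erythroid genes (0) were 1 with DESeq2, 51 without the filter, 6 with the part and 9 with the block; 0 to 3 (marrow 11). Macrophage genes (516) were 875 without the filter and 802 with all 15 libraries; 324 (gap 11) to 629 (marrow 11). Genes of plasmacytoid dendritic cells (204) were 359 without the filter, 5 with stricter cells, 336 with the part, 552 with the block and 75 with all 15 libraries; 83 (gap 5) to 246 (marrow 11). The block also brought in the erythroid interferon list (adjusted p = 0.00087), monocyte oxidative phosphorylation (0.015), mitochondrially encoded transcripts in plasmacytoid dendritic cells (0.025) and macrophage immediate early (0.041) and G2M (0.044) lists, and ended the call of erythroid S phase (0.051) and, in plasmacytoid dendritic cells, of hemoglobin (0.064) and immediate early genes (0.055); it changed the call of no other list in this comparison. Without single libraries, erythroid Hbb-bt ran from -0.0445 to 0.13, Hbb-bs from -0.0371 to 0.19, Hba-a1 from -0.0419 to 0.27 and Hba-a2 from -0.15 to 0.21 (lowest without gap 11), and list adjusted p from 2.2e-06 to 0.794 (erythroid granules, reversed without gap 11) and from 1.7e-08 to 0.982 (neutrophil interferon; reversed without marrow 5, 0.104).

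CD71 antibody, rigid: erythroid genes (6) were 747 with DESeq2, 3 with RLE, 1182 without the filter, 0 with doublets kept, 607 with stricter cells, 0 without genes of other classes, 1 without doublet-prone clusters, 0 with the part and 0 with only the 2 groups; 0 (any isotype library) to 1828 (CD71 2). The neutrophil share difference (-1.24) was 0.991 without doublet-prone clusters and -5.84 (CD71 12) to 5.27 (CD71 6); the erythroid share difference -1.70 (6) to 1.10 (2), 0.203 without 12 and 0.0924 without isotype 11. Monocyte granules: adjusted p 1.0e-05 to 0.626 (reversed without CD71 6).

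Compliant against rigid: erythroid genes (0) were 356 with DESeq2, 683 without the filter and 1286 with only the 2 groups; 0 to 1 (rigid isotype 1). Neutrophil genes (0) were 15 with DESeq2, 1 without the filter and 11 with the part. Monocyte genes (0) were 19 with DESeq2. Interferon lists: neutrophils 2.3e-07 to 0.588 (19-20 reversed, 0.303); monocytes 8.8e-07 to 0.899 (19-20, reversed).

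CD71 antibody, compliant: erythroid genes (0) were 7 without the filter and neutrophil genes (0) 13 with DESeq2. Hba-a2 (-0.00) was 0.0037 with DESeq2, 0.0037 with RLE, 0.013 without the filter, 0.33 with stricter cells, 0.017 without doublet-prone clusters and 0.37 with the part. Without both small compliant libraries, Hba-a1 was -0.16, Hbb-bs -0.10 and Hbb-bt -0.10. Without single libraries Hbb-bt ran from -0.0376 to 0.19, Hbb-bs from -0.0368 to 0.19, Hba-a1 from -0.0887 to 0.16 and Hba-a2 from -0.14 to 0.10 (lowest without 17-18). The 433 erythroid genes differing between fixations were 970 with DESeq2, 1304 without the filter, 1521 with stricter cells, 1 with doublets kept, 2 without doublet-prone clusters and 1 with the part; 0 (5 isotype libraries) to 1805 (rigid CD71 2).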

Other observations

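Natural killer cells made up 0.652% ± 0.0314 (n = 3) of gap and 0.5004% ± 0.0556 (n = 3) of marrow cells (exact permutation p = 0.1). In gap neutrophils, all 13 mitochondrially encoded transcripts were lower than in marrow (adjusted p = 0.00063; 8 fell with the mouse as a block; adjusted p = 0.605 with an estimated correlation), with mt-Cytb at 342 CPM ± 26.3 against 419 CPM ± 47.6.

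Macrophages of rigid gaps with the CD71 antibody had lower G2M genes than with isotype for 42 of 44 members (adjusted p = 3.2e-13; adjusted p = 0.81 with an estimated correlation), while S100 and granule transcripts of neutrophils in them stood at 29965 CPM ± 21564 against 14839 CPM ± 8575. In compliant against rigid isotype gaps, macrophage G2M genes were lower for 43 of 44 (adjusted p = 7.5e-08; adjusted p = 0.661 with an estimated correlation), and 13 of 15 extracellular matrix and osteogenesis genes higher (adjusted p = 0.011; adjusted p = 0.661 with an estimated correlation). S100 and granule transcripts stood at 27743 CPM ± 15633 against 14839 CPM ± 8575. No gene was called in either.

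Libraries up to sample number 10 differed from later ones in a few abundant transcripts: Gm42418 was 8.41 times higher in the early part of the series, AY036118 5.70 times, Lars2 5.76 times, mt-Atp8 3.65 times and the histone gene Hist1h1e 2.80 times.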
